A study of Strongylocentrotus purpuratus with 17 samples.

How the data were processed

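Nascent transcription was measured in embryos of the purple sea urchin, Strongylocentrotus purpuratus, by PRO-seq, in which RNA polymerases already engaged on the DNA are allowed to run on in isolated nuclei with biotin-labelled nucleotides and the labelled RNA is sequenced. The labels describe 17 libraries in 6 groups. The 13 libraries behind the 4 lists used here were 2 of embryos at 8 h, 4 at 12 h, 5 at 20 h and 2 at 72 h, from 1, 3, 4 and 2 biological replicates by their titles, grown at 15 °C. The other 4 libraries, 2 quick PRO-seq libraries at 72 h and 2 of adult red spherule cells, were not analysed here. Groups were taken from the sample titles, since the labels' tissue field names the 8 h stage for libraries whose titles name another stage.

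The deposited files used here were 4 peak lists, 1 per stage. Per the labels, each list belongs to all PRO-seq libraries of its stage and holds dREG peaks. dREG is a classifier that finds transcriptional regulatory elements, promoters and enhancers alike, from the paired divergent transcription around them. Per the labels, positions are on the Sp 5.0 genome, and the 12 h and 20 h libraries were samples of earlier work taken through the same genome. The read aligner, the caller's settings and the way libraries were pooled are not given in the sources used here. Each deposited list had 3 columns, the scaffold, the start and the end, with no score, p-value or read number, so the depth behind an element is unknown. Positions were in steps of 10 bp, and no list held overlapping or repeated elements. Elements 100 bp or less apart remained, 923 pairs at 8 h, 422 at 12 h, 707 at 20 h and 42 at 72 h. A list pools its libraries, so no spread between replicates could be computed, no test between stages was made and no p-value is given. Shares carry Wilson 95% intervals, which cover counting error only.

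Genes came from a table of the RefSeq annotation of the same assembly, Spur_5.0, which gave a start and an end per gene but no scaffold and no strand. The table lists genes in runs in which the start position increases. Each run of at least 900 genes was placed on the scaffold where the largest share of its gene ends lay within 500 bp of an 8 h element. This gave 21 runs on 21 different scaffolds, with 30064 of 33490 genes. The share on the chosen scaffold was 18.8% to 33.6%, against 8.3% to 14.1% on the next best, a ratio of 1.67 to 3.73. Offered only these 21 scaffolds, the 12 h, 20 h and 72 h lists each chose the same scaffold for 21 of 21 runs. Of their elements 76.9%, 61.2% and 90.9% overlapped an 8 h element, so this was not an independent check. When the runs were broken into pieces of 100 genes, 258 of 288 pieces were best placed on the scaffold of their run. Gene positions given here therefore rest on an inferred scaffold, and the 8 h list was used to infer it. Genes outside the 21 scaffolds were not analysed. The scaffolds span 828.1 Mb.

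The plan had promoter windows at transcription start sites and separate shares for exons and introns. Without strand or exons, windows of 500 bp either side of both ends of each gene were used in their place. An element overlapping such a window is called a gene-end element. Other elements were placed inside or between genes by their midpoint. Sequence motifs were planned too and were not analysed, because no genome sequence was used here. Overlap between lists meant at least 1 bp. The background for location and overlap was the mean of 200 random placements of each element on its own scaffold. The neighbourhood of a gene was its body and 10 kb either side, and an element counted there by its midpoint, so that 1 element could count for several genes.

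The 24 gene lists were fixed before the data were examined and matched by symbol. Most genes of the annotation carry only a locus number, so the lists shrank: 20 skeletogenic, 6 pigment cell and other mesoderm, 13 endoderm and gut, 19 ectoderm, 8 apical plate and nervous system, 14 early zygotic, 22 homeobox, 9 signalling, 8 immune and coelomocyte and 14 gamete genes were placed. The lists of forkhead, histone, ribosomal protein, cell cycle, Sox, Hox, cilium, neuronal effector and heat shock genes had fewer than 5 members each. No member was matched for muscle, digestive enzymes, mitochondrial respiration, splicing or transposon-derived genes. The homeobox, Hox, forkhead, Sox and signalling lists were also joined as 38 regulatory genes after the files had been seen. Lists share members. For lists of at least 5 genes, the mean number of elements was given as a percentile among 10000 random lists of protein-coding genes drawn from the same of 10 length classes. At single stages the median was ranked in the same way. A percentile describes these pooled lists and is not a p-value. The same was done for the change between stages in the mean and in the share of genes with a gene-end element, the latter without alternatives. The change in the mean was a difference and not a ratio. A list with more elements at the earlier stage therefore has more to lose when fewer elements are called later.

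Genes were named by a rule also fixed beforehand. Per comparison it took up to 2 members of each list with a gene-end element only at the later stage and up to 2 only at the earlier stage, and, among genes outside the lists with an informative name rather than a locus number, the 5 that gained and the 5 that lost most neighbourhood elements. Per stage it took the 10 genes with most elements, the 3 leading members of each list and the 3 widest elements. Other genes are said to have been chosen after their values were seen.

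Alternatives covered windows of 200 and 1000 bp, protein-coding genes only, elements of at least the median width of 640 bp, joining within 500 bp, scaffolds of at least 1 Mb, other overlap rules, neighbourhoods without flanks or with 50 kb, assignment to the nearest gene end, and lists thinned at random to 4425 elements in 100 draws. The steps were tested on simulated data over 30064 genes. All 21 runs were placed back on their scaffolds, a simulated sharing of 39.9% was measured as 40.0%, and 2.0% of unchanged lists of 15 genes lay past the upper limit of the central 95% of random lists. Those lists were drawn at random, and each gene had a count of its own. The simulation thus did not cover lists whose genes share elements or carry curated symbols. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and Matplotlib 3.10.9.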

Results

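PRO-seq maps RNA polymerases engaged in transcription, and the peaks called from it mark promoters and enhancers in use. Elements were listed for sea urchin embryos at 8 h (2 pooled libraries), 12 h (4 libraries), 20 h (5 libraries) and 72 h (2 libraries). By their titles these came from 1 biological replicate at 8 h, 3 at 12 h, 4 at 20 h and 2 at 72 h. The series' design follows active elements through development, and the comparisons below take each stage with the next. Each stage had 1 list made from pooled libraries, so no value has a replicate error. Read depth behind the lists is unknown, and a difference between lists can therefore hold a difference in depth. Per the labels, the 12 h and 20 h libraries were samples of earlier work. The comparisons of 8 h with 12 h and of 20 h with 72 h can therefore also hold a difference between sets of libraries.

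The 8 h embryos had the longest list, 56158 elements covering 41.29 Mb. The 12 h list held 30570 elements over 23.19 Mb and the 20 h list 37796 over 27.32 Mb. The 72 h list held 4425 elements over 2.72 Mb, 12.69-fold fewer than at 8 h. On the 21 scaffolds to which genes could be assigned, this was 62.83, 34.33, 43.13 and 5.18 elements per Mb at 8 h, 12 h, 20 h and 72 h. Median widths were 640, 660, 620 and 560 bp.

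Gene ends were the favoured location at every stage, and most of all at 72 h. A gene-end element, within 500 bp of either end of an annotated gene, made up 26.9% of the 8 h list (95% Wilson interval 26.5 to 27.3), 37.1% of the 12 h list (36.5 to 37.6), 32.2% of the 20 h list (31.8 to 32.7) and 66.8% of the 72 h list (65.4 to 68.2). Random placement gave 11.3%, 11.4%, 11.3% and 10.8%. Elements inside genes but away from their ends were 34.6%, 30.5%, 34.4% and 17.1% of the lists, below the 43.5%, 44.0%, 44.7% and 46.0% of random placement. Elements between genes were 38.5%, 32.4%, 33.4% and 16%. Elements at gene ends were wider than the others, with medians of 860 against 610 bp at 8 h and 580 against 540 bp at 72 h.

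**Figure D1:**
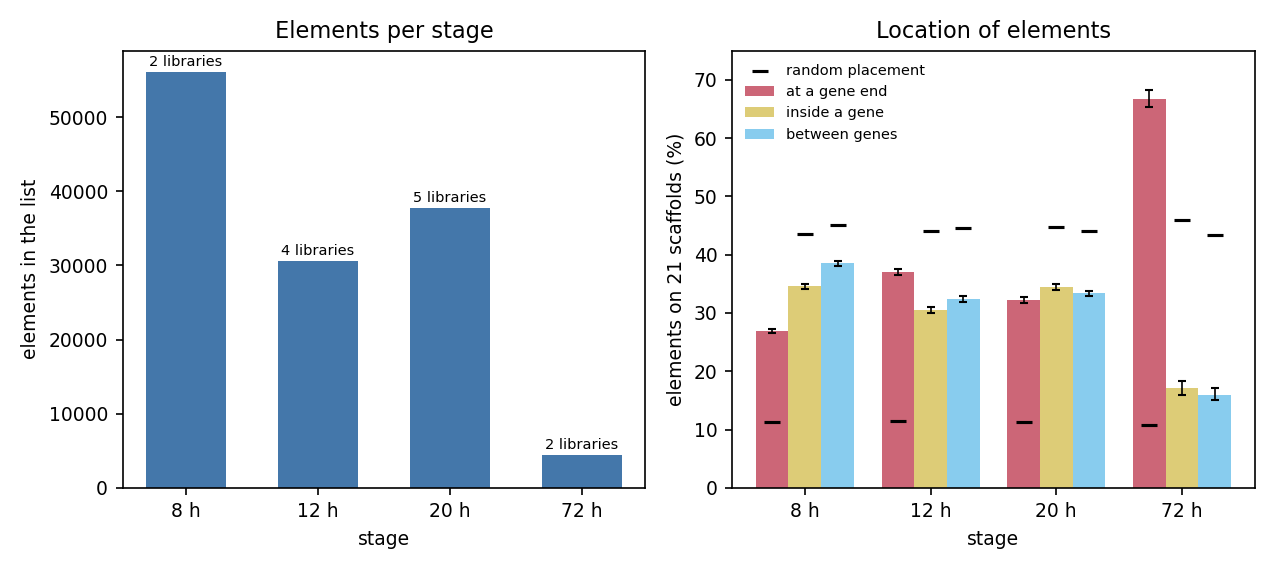
Left, number of elements in the list of each stage, with the number of pooled libraries above each bar. Right, percent of elements on 21 scaffolds that lay at a gene end, inside a gene or between genes, with 95% Wilson intervals as error bars and black marks for the mean of 200 random placements. The gene-end bar stands at 26.9% at 8 h and at 66.8% at 72 h.

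The union of the 4 lists held 75391 regions. Of these, 58.7% were called at 1 stage, 19.2% at 2, 17.3% at 3 and 4.9% at all 4. The most common patterns were 8 h alone with 26223 regions, 8 h with 12 h and 20 h with 12725, and 20 h alone with 12625. Only 158 regions were called at 72 h alone. The 3665 regions called at all 4 stages lay at a gene end in 74.8% of cases (95% interval 73.4 to 76.2), against 15.3% for random placement of the same regions. Regions called at 8 h alone and on the same scaffolds lay at a gene end in 12.7% of cases (12.3 to 13.2), against 10.4%. Without the 72 h list, a choice made after seeing the data, 21.8% of regions were called at every remaining stage.

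From 8 h to 12 h, more elements left the list than entered it. Of the 8 h elements, 41.9% (95% interval 41.5 to 42.3) overlapped a 12 h element, against 5.04% for random placement, and 32614 did not. Of the 12 h elements, 76.9% (76.4 to 77.3) were already called at 8 h. Gene-end elements were found at 12263 protein-coding genes at 8 h and 9817 at 12 h. They were found at both stages for 9138 genes, at 8 h alone for 3125 and at 12 h alone for 679. With both lists thinned to 4425 elements, 6.2% of the 12 h elements were shared, as random thinning leaves few elements to meet.

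The developmental gene lists held fewer elements at 12 h than at 8 h, as did protein-coding genes in general, with means of 2.55 and 1.53. Skeletogenic genes, which act in the cells that build the larval skeleton, had a mean of 3.95 elements in their neighbourhood at 8 h and 1.95 at 12 h, with fewer at 17 of 20 genes. Among them Alx1, a homeobox regulator of these cells (NW_022145603.1, 14657058 to 14712320), went from 6 elements to 2 and lost its gene-end element. COLP1alpha, a collagen gene, went from 3 to 1 and lost its own, while the biomineralization gene msp130 had a gene-end element only at 12 h, with 3 and 2 neighbourhood elements. Endoderm and gut genes had means of 5.38 and 2.69, with blimp1/krox (NW_022145607.1, 33414785 to 33447745), a zinc finger regulator of endoderm, at 10 and 6 and without a gene-end element at 12 h. Signalling genes had means of 5.22 and 2.00, and the TGF-beta family ligand gene DVR1 went from 5 to 2. Homeobox genes went from 4.55 to 2.64, and pigment cell and other mesoderm genes from 6.17 to 2.67, fewer at 6 of 6 genes. Gamete genes had means of 4.93 and 2.57, and the sperm adhesion gene BND, which encodes bindin, had 4 and then 1 while REJ9 had 6 and then 0.

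Other lists held fewer elements at 12 h too, but less far from random lists or with more exceptions. The 19 ectoderm genes had means of 4.53 and 2.89, with fewer elements at 12 genes and more at 4, and Not, a homeobox gene, had a gene-end element only at 12 h. Early zygotic genes had means of 4.86 and 3.50, and Tcf/Lef, the nuclear effector of Wnt signalling, lost its single element. Immune and coelomocyte genes had means of 3.62 and 3.25, with fewer elements at 3 of 8. Gene-end elements lay at 4 of 4 histone genes at 8 h and 2 of 4 at 12 h, H2A and H2B-1 having lost theirs. FoxJ1, a regulator of motile cilia, had 7 and 4 neighbourhood elements and gained a gene-end element at 12 h, as did the replication gene Cdc6 with 4 and 3. Outside the lists, among genes with an informative name rather than a locus number, FRK (2 to 5) and VEB4 (5 to 8) gained most, and spec2d (8 to 0), sfk3 (8 to 1) and SPIH (7 to 1) lost most. The difference of the means lay at the 2.29th percentile of random lists of like length for skeletogenic, the 0.32nd for pigment cell and other mesoderm, the 0.05th for endoderm, the 0.48th for homeobox, the 0.17th for signalling and the 0.00th for regulatory genes. It lay at the 5.88th for ectoderm, the 19.13th for apical, the 11.29th for early zygotic, the 3.56th for gamete and the 93.93rd for immune genes. A low place can follow from a higher 8 h mean, since such a list had more to lose. The ratio of 12 h to 8 h mean was 0.58 for homeobox genes, with random lists going from 2.65 to 1.59. It was 0.38 for signalling genes (random 3.27 to 1.92). With lists thinned to equal numbers the 6 lists with the lowest percentiles lay between the 28.72nd and the 45.12th percentile, inside the central 95% of random lists. Skeletogenic (10.97), pigment cell and other mesoderm (10.01) and homeobox genes (2.64) lay inside it with the gene body only, and pigment cell and other mesoderm genes (2.67) with 50 kb either side. Ectoderm, apical and early zygotic genes lay outside it with 50 kb either side, at the 0.02nd, 0.01st and 0.08th, and with the nearest gene end only, at the 0.00th, 0.01st and 0.00th. For the share of genes with a gene-end element, the difference of ectoderm genes lay at the 98.78th and those of the other 10 lists inside the central 95%.

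From 12 h to 20 h the developmental lists again held more elements. Of the 12 h elements, 60.2% (59.6 to 60.7) overlapped a 20 h element, and 49.3% (48.7 to 49.8) of the 20 h elements had been called at 12 h, against 5.15% for random placement. Protein-coding genes with a gene-end element numbered 9817 at 12 h and 10692 at 20 h, with 8543 shared, 1274 at 12 h alone and 2149 at 20 h alone. At 20 h, 12783 elements, 33.8% of the list (33.3 to 34.3), had been called at neither earlier stage. Among gene-end elements alone, 75.2% of the 20 h elements had been called at 12 h.

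Skeletogenic genes held more elements at 20 h at 17 of 20 genes and fewer at none, and their mean went from 1.95 to 4.95, a ratio of 2.54, a difference of 3.0 where random lists of like length had a mean difference of 0.51. P16, a gene of the biomineralizing cells (NW_022145615.1, 10667000 to 10669900), had 0 elements at 12 h and 7 at 20 h. SM29, a spicule matrix gene (NW_022145602.1, 7916731 to 7927690), had 2 and 8. Both had a gene-end element only at 20 h in this comparison. Chosen after their values were seen, the spicule matrix genes SM50, SM37 and PM27, between positions 7408098 and 7454605 of the same scaffold, had 3, 0 and 1 at 12 h and 6, 5 and 6 at 20 h, partly the same elements. The neighbourhoods of COLP3alpha and COLP4alpha overlap too, as do those of COLP1alpha and COLP2alpha. Random lists drew each gene on its own, so shared elements can raise the place of this list. In other lists neighbourhoods overlap for AMAS2 and AMAS4 (immune), FGFR and FGFRL1 (signalling and regulatory), SPEC1 and spec2c (ectoderm) and H2A and H4 (histone). Where such lists have percentiles, shared elements can move those too, up or down. The regulator gene erg had 1 and 2 and msp130 2 and 2, and both had a gene-end element at 12 h and not at 20 h. In other mesoderm, the 6 genes had means of 2.67 and 7.17, more at 5 genes. GATAc, a GATA factor gene expressed in nonskeletogenic mesoderm (NW_022145612.1, 11500266 to 11556165), had 2 elements at 12 h and 17 at 20 h, among the 10 highest numbers of any gene at that stage.

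**Figure D2:**
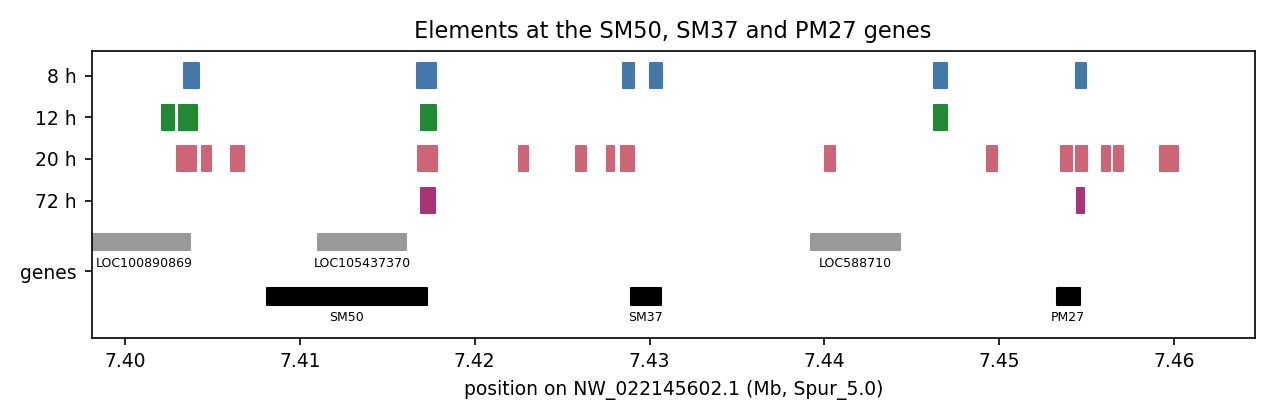
Elements of the 4 lists (coloured bars, 1 row per stage) and annotated genes (SM50, SM37 and PM27 in black, others in grey) along NW_022145602.1, positions 7398098 to 7464605 in Mb. The region was chosen after its values were seen, and it holds 6 elements at 8 h, 4 at 12 h, 15 at 20 h and 2 at 72 h.

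Endoderm and gut genes had means of 2.69 at 12 h and 5.92 at 20 h, with more elements at 11 of 13 genes and fewer at none. FoxA, a forkhead regulator of endoderm (NW_022145611.1, 31436173 to 31439051), had 2 and 8, and GATAe had 2 and 9. Ectoderm genes had means of 2.89 and 5.42, more at 14 of 19 and fewer at 4, with Dlx at 4 and 13 and Tbx2/3 at 5 and 13. SPEC1, a calcium-binding protein gene of the ectoderm, had 4 at both stages and a gene-end element at 12 h and not at 20 h, as had Not with 3 and 2. Apical plate and nervous system genes had means of 2.62 and 5.38, with otx, a homeobox gene, at 8 and 12 and FoxJ1 at 4 and 8. Early zygotic genes had means of 3.50 and 5.21, and SpRunt-1 had 4 and 9. Homeobox genes went from 2.64 to 4.77 and signalling genes from 2.00 to 4.44.

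Immune and gamete genes stood apart from these lists. Immune and coelomocyte genes had means of 3.25 and 1.62, with fewer elements at 7 of 8. Among the 7, AMAS2 and AMAS4 have overlapping neighbourhoods and count partly the same elements. AMAS2, which encodes an amassin of coelomic cell clotting, went from 4 to 1 and SRCR12, a scavenger receptor gene, from 4 to 3, and both lost the gene-end elements they had at 12 h. Gamete genes had a mean of 2.57 at both stages, with rej2 at 2 and 4 and a gene-end element at 20 h and not at 12 h. Among histone genes, H4 had 1 and 2 and lost its gene-end element, and Cdc6 had 3 and 2 and lost its own. Outside the lists, among genes with an informative name, Mir2003 (0 to 7), Elk (5 to 11), FSCN1 (6 to 11), SPIH (1 to 6) and eif4a (2 to 6) gained most, and arc2 (4 to 0), VEB4 (8 to 4), cyiiib (3 to 0), eif4e1 (4 to 1) and Mir981 (3 to 0) lost most. The difference of the means lay at the 100th percentile of 10000 random lists for skeletogenic, endoderm, ectoderm, apical, homeobox and regulatory genes, at the 99.98th for pigment cell and early zygotic genes, at the 99.59th for signalling genes, at the 10.46th for gamete genes and at the 0.01st for immune genes. With lists thinned to equal numbers, only the regulatory genes stayed outside the central 95% of random lists, at 98.47, with skeletogenic genes at 96.2, endoderm genes at 94.62 and immune genes at 6.53. Early zygotic genes lay inside it also with the gene body only (96.22), as did immune genes (11.41), which lay inside it with 50 kb either side too (19.66), and gamete genes lay outside it with the gene body only (1.73) and with the nearest gene end only (1.87). For the share of genes with a gene-end element, the difference of immune genes lay at the 2.08th and those of the other 10 lists inside the central 95%.

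**Figure D3:**
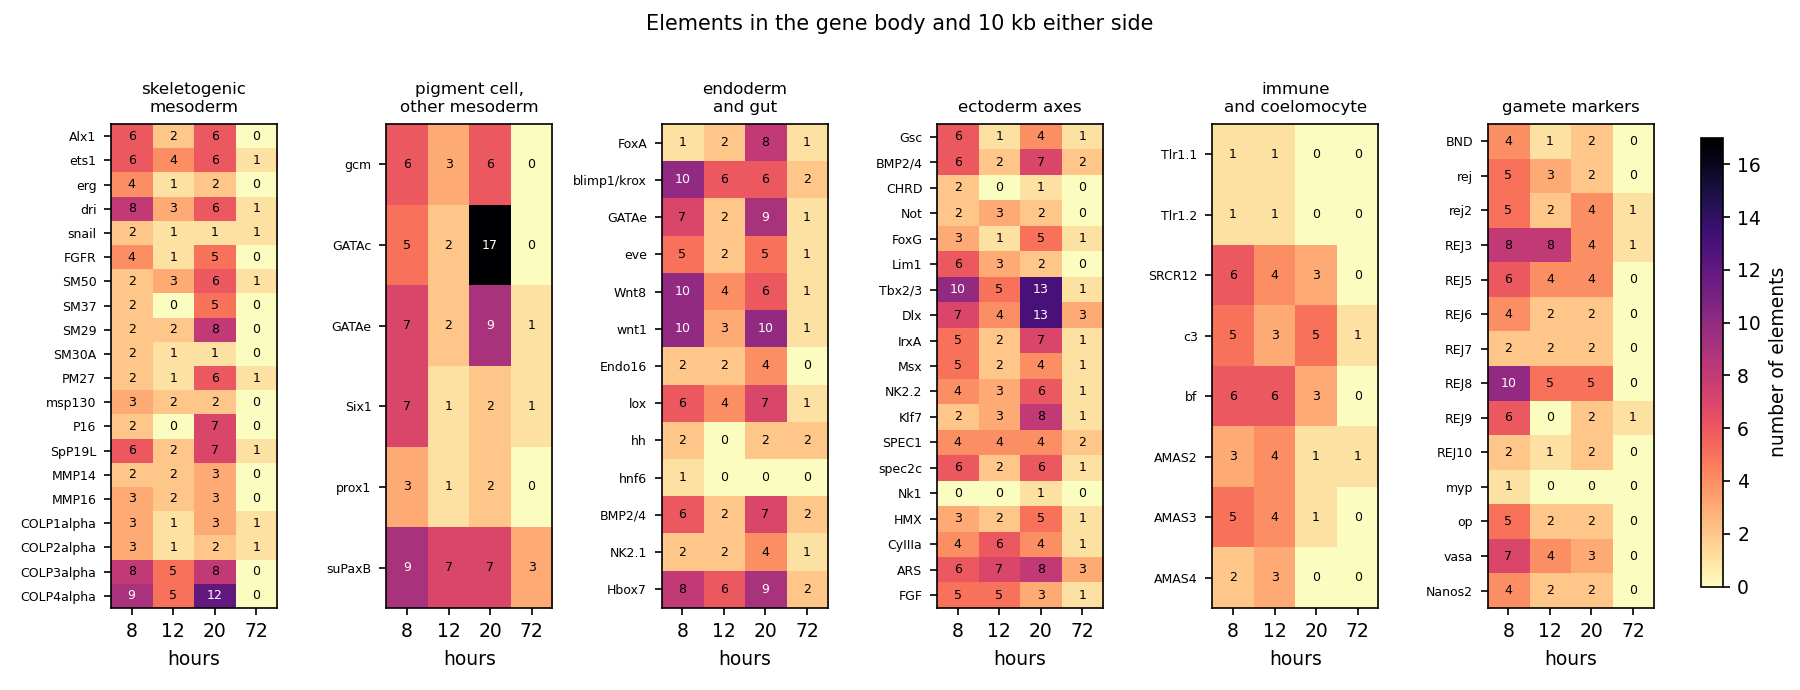
Number of elements in the body and 10 kb either side of each placed gene of the skeletogenic, pigment cell and other mesoderm, endoderm, ectoderm, immune and gamete lists at 8, 12, 20 and 72 h (colour and printed number). GATAc stands out with 17 at 20 h, and the 72 h column holds at most 3 in any gene shown.

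Few of the 20 h elements were called again at 72 h, and most of the 72 h elements lay at gene ends. Of the 20 h elements, 10.8% (10.5 to 11.1) overlapped a 72 h element, against 0.73% for random placement. The 4425 elements at 72 h could meet only a small part of the 37796 elements at 20 h, so list length limits this share. Of the 72 h elements, 93.0% (92.2 to 93.7) overlapped a 20 h element, 87.8% a 12 h element and 90.9% an 8 h element, and 3.6% (3.1 to 4.2) overlapped none. When 50% of both elements had to overlap, 60% of the 72 h elements were shared with 20 h. Protein-coding genes with a gene-end element numbered 10692 at 20 h and 3076 at 72 h, 3019 at both, 7673 at 20 h alone and 57 at 72 h alone. With lists thinned to equal numbers, genes of all kinds with a gene-end element numbered 1208, 1691 and 1466 at 8 h, 12 h and 20 h, below the 3336 at 72 h. Thinning drops elements whatever their width, while 32.8% of the widest and 2.6% of the narrowest quintile of 20 h elements were found at 72 h. Thinned lists therefore do not stand for lists of lower depth. Of the protein-coding genes, 2922 had one at all 4 stages and 10857 had none at any stage.

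No list gene had more neighbourhood elements at 72 h than at 20 h, and 95 of 107 had fewer. The fall was general: over all protein-coding genes the mean went from 1.85 to 0.27. The share with any neighbourhood element went from 71.3% to 21.9%. Skeletogenic genes had a mean of 0.40, with COLP4alpha from 12 to 0 and COLP3alpha from 8 to 0, while COLP1alpha and COLP2alpha had a gene-end element at 72 h and not at 20 h. Pigment cell and other mesoderm genes had a mean of 0.83, and gcm, a regulator of pigment cells (NW_022145598.1, 34773541 to 34780207), went from 6 to 0. Endoderm and gut genes had a mean of 1.15, and 10 of 13 had a gene-end element at 72 h, against 9 at 20 h. In that list the Hedgehog ligand gene hh (NW_022145612.1, 3341495 to 3362363) had 2 elements at both stages and a gene-end element at 72 h alone of the 4 stages, blimp1/krox had 6 and 2 and regained a gene-end element, and Wnt8 went from 6 to 1. Ectoderm genes had a mean of 1.11 and a gene-end element at 14 of 19, with Lim1 from 2 to 0. Apical and early zygotic genes had means of 1.00 and 1.29, with SpAN, a metalloprotease gene, at 4 elements.

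Homeobox genes had a mean of 0.95 at 72 h, with hox1 from 4 to 0, and signalling genes 0.78, with the receptor gene FGFR from 5 to 0. Immune genes had a mean of 0.25 and gamete genes 0.21, with REJ8 from 5 to 0, REJ5 from 4 to 0 and REJ9, which had a gene-end element at 72 h and not at 20 h, from 2 to 1. Among the short lists soxd1 went from 8 to 0, fkh1 and cdk4 from 2 to 0 and rpl36 from 1 to 0. Outside the lists, among genes with an informative name, Elk (11 to 1), FSCN1 (11 to 2), SHR3 (10 to 1), duox1 (9 to 1) and Sdc (11 to 3) lost most, and none gained. The difference of the means lay at the 0.00th percentile of random lists for skeletogenic, endoderm, ectoderm, early zygotic, homeobox and regulatory genes. It lay at the 0.04th for pigment cell and other mesoderm, the 0.07th for apical, the 2.45th for signalling, the 42.23rd for gamete and the 73.82nd for immune genes. A low place here does not show a larger share lost, since lists with more elements at 20 h had more to lose. The ratio of later to earlier mean was 0.19 for regulatory genes, with random lists going from 1.97 to 0.28. It was 0.25 for early zygotic (random 1.58 to 0.24) and 0.08 for skeletogenic genes (random 2.29 to 0.31). Ratios were not ranked among random lists. With lists thinned to equal numbers, endoderm, ectoderm, early zygotic, homeobox and regulatory genes lay on the opposite side, at the 97.9th, 98.47th, 100th, 99.03rd and 99.7th. Skeletogenic genes (7.97), pigment cell and other mesoderm genes (44.88), apical genes (90.35) and signalling genes (76.97) then lay inside the central 95%, as did skeletogenic (3.97) and signalling genes (6.62) with the gene body only. For the share of genes with a gene-end element the difference lay high, at the 100th percentile for endoderm, the 99.46th for ectoderm, the 99.33rd for early zygotic, the 98.57th for homeobox and the 99.76th for regulatory genes. It lay at the 97.56th for immune genes, of which none had such an element at 20 h, and inside the central 95% for the other 5 lists.

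**Figure D4:**
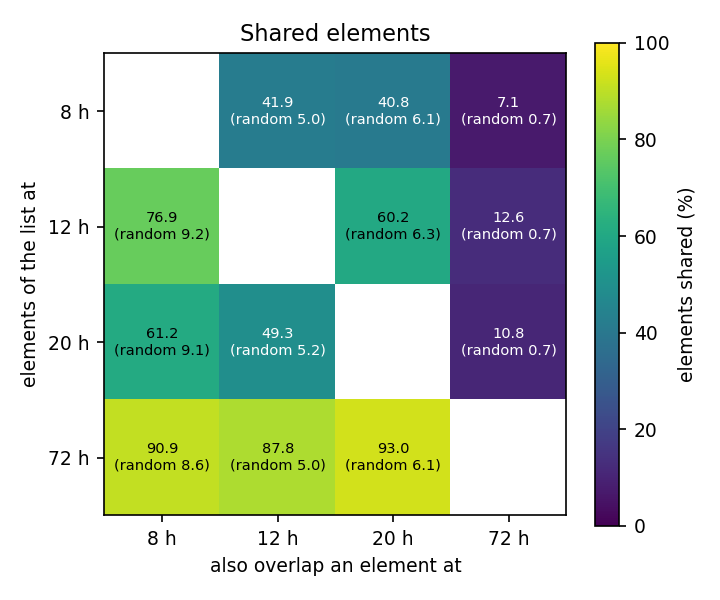
Percent of the elements of each list (rows) that overlapped at least 1 bp of an element of another list (columns), with the mean of 200 random placements in brackets. The row of the 72 h list lies between 87.8% and 93.0%, and the column of the 72 h list between 7.1% and 12.6%. The shortness of the 72 h list, 4425 elements, limits the values of that column.

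Within single stages, most developmental lists held more elements than random lists of protein-coding genes of like length. Genes with a curated symbol did so too, since lists of 211 others, matched in length to the regulatory genes, had means of 3.58, 2.28, 2.95 and 0.48 at 8 h, 12 h, 20 h and 72 h. This set includes developmental regulators outside the 38, such as GATAc and blimp1/krox. Only the regulatory genes were compared with it. The 38 regulatory genes had means of 4.76, 2.53, 4.89 and 0.95 at 8 h, 12 h, 20 h and 72 h, against 2.71, 1.61, 1.97 and 0.28, at the 100th, 99.98th, 100th and 100th percentiles. Early zygotic genes lay at the 100th percentile at each stage and endoderm genes between the 99.18th and 100th. Ectoderm and homeobox genes lay between the 99.93rd and the 100th. Skeletogenic genes lay at the 97.22nd, 70.23rd, 100th and 75.63rd, and signalling genes at the 99.39th, 58.62nd, 98.77th and 96.16th. Pigment cell and other mesoderm genes lay at the 99.8th, 87.32nd, 99.95th and 95.18th, and apical genes at the 98.42nd, 97.0th, 99.99th and 99.46th. Immune genes lay at the 85.55th, 99.41st, 25.84th and 44.93rd, and no immune gene had a gene-end element at 20 h or 72 h. Gamete genes lay at the 98.8th, 88.68th, 48.09th and 21.47th.

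Several of these places depended on the choices made. With lists thinned to equal numbers, endoderm genes lay at the 88.2nd percentile at 8 h and the 84.8th at 12 h, ectoderm genes at the 91.15th and 96.15th, homeobox genes at the 91.65th and 88.38th and regulatory genes at the 93.93rd at 12 h. At 8 h, pigment cell and other mesoderm genes lay at the 68.75th, apical genes at the 82.78th, early zygotic genes at the 96.17th, gamete genes at the 74.2nd and signalling genes at the 83.5th. Immune genes lay at the 90.7th at 12 h, and at 20 h pigment cell and other mesoderm genes lay at the 97.03rd, apical genes at the 96.85th and signalling genes at the 88.42nd, all of these values inside the central 95% of random lists. With the gene body alone, 12 percentiles came inside, among them skeletogenic genes at the 93.84th at 20 h, ectoderm genes at the 90.56th at 72 h and regulatory genes at the 89.11th at 12 h. With each element given only to the nearest gene end, skeletogenic genes lay at the 98.39th at 12 h and the 97.84th at 72 h. With the median in place of the mean, endoderm (79.41), homeobox (88.51) and regulatory genes (90.08) came inside the central 95% at 12 h. Apical genes (92.8) did so at 8 h. The other percentiles of the median stayed inside it or outside it on the same side.

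The short lists have no percentile. The 4 histone genes had gene-end elements at 4, 2, 1 and 1 genes over the 4 stages, the 1 at 20 h and 72 h being the variant gene H2A.F/Z. The 3 ribosomal protein genes had them at 3, 3, 3 and 2 genes, and the 3 cell cycle genes at 2, 3, 2 and 1. The 2 Hox genes had mean neighbourhood numbers of 5.0, 3.5, 6.5 and 1.0, the 3 Sox genes 7.0, 4.0, 6.0 and 1.33 and the 4 forkhead genes 3.25, 2.0, 5.75 and 1.0. The cilium list held FoxJ1 alone, the heat shock list hsp110 with 3, 3, 4 and 1 elements, and the neuronal list SNAP-25 with 1, 1, 0 and 0.

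Genes with the most elements mostly carried locus numbers. LOC583085 and LOC585077 led at 8 h with 19 each, LOC581963 and LOC582205 at 12 h with 13 each and LOC581963 at 20 h with 27. A longer gene has a wider neighbourhood, and these numbers were not set against length. LOC583085 spans 300967 bp, LOC585077 113109 bp, LOC581963 122745 bp and LOC582205 22223 bp. A high number here therefore does not show a dense set of elements. At 72 h LOC105437105 led with 9, and 7 others of the 10 leading genes lay inside it or close by on NW_022145597.1, so that they count largely the same elements. The widest elements were 3590 bp at 8 h (NW_022145611.1, 265651 to 269240, overlapping LOC115929535), 3670 bp at 12 h (NW_022145603.1, 19069351 to 19073020, overlapping LOC751836), 2950 bp at 20 h (NW_022145597.1, 31676591 to 31679540, overlapping LOC577764) and 2110 bp at 72 h (NW_022145596.1, 3014371 to 3016480). The second widest at 72 h, 2000 bp, overlapped HMG1 (NW_022145596.1, 1587321 to 1589320).

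Wide elements were found again at the next stage more often than narrow ones. From the narrowest to the widest quintile, the share of 8 h elements also called at 12 h went from 16.2% (15.5 to 16.9) to 80.1% (79.4 to 80.8). For 12 h elements at 20 h it went from 32.2% (31.1 to 33.4) to 91.4% (90.6 to 92.0). For 20 h elements at 72 h it went from 2.6% (2.2 to 3.0) to 32.8% (31.8 to 33.9).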

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

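No paired analysis was possible because each list pools the libraries of its stage and holds no column per library. Leaving out single libraries was impossible for the same reason. The planned motif alternatives (a longer central window, elements outside promoter windows and a background from the flanks) were not run, since motifs were not analysed. Read depth behind the lists is unknown, and it limits every comparison of numbers between stages. The setting without the 72 h list was chosen after seeing the data. Where no construction of an alternative shows the cause of a difference given below, the cause was not tested.

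Numbers of elements at 4 stages stayed within 1.5 times of those reported when elements within 500 bp were joined and when only scaffolds of at least 1 Mb were used. Keeping only elements of at least the median width left, by construction, 28673, 16369, 18198 and 1521 elements at 8 h, 12 h, 20 h and 72 h, with 37.4, 49.4, 43.9 and 74.8% at gene ends. In that setting 77.5% of 12 h elements were shared with 8 h and 53.1% of 20 h elements with 12 h, and 1385 genes had a gene-end element at 72 h. Gene-end shares in the same order of stages were 23.5, 33.6, 29.3 and 63.7% with the 200 bp window, 31.9, 42, 36.7 and 70% with the 1000 bp window and 24, 33.5, 29.7 and 62.6% with protein-coding genes only. A narrower window or fewer genes leaves less sequence to meet. With elements joined, the shares at 8 h, 12 h and 20 h were 27.6, 37.9 and 33.8%. The 72 h list had the highest gene-end share in each setting. Shares of lists thinned to equal numbers stayed within their intervals, but random thinning keeps the expected share by construction. Thinning also removed nothing from the 72 h list, so this setting does not test whether list length affects the share.

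The shares of 12 h elements found at 8 h and of 20 h elements found at 12 h were 77.6% and 50.9% with elements joined and 78.1% and 50.4% with a gap of up to 200 bp allowed. With overlap of at least 50% of both elements, they were 69.9% and 44%, and 60% of 72 h elements were found at 20 h. Away from gene ends the 3 shares were 69.9%, 36.7% and 87%, and at gene ends 89.7%, 75.2% and 96.4%. With lists of equal number they were 6.2%, 7.2% and 10.9%, because thinning leaves few elements to meet. Thinning likewise left 1208, 1691 and 1466 genes with a gene-end element at 8 h, 12 h and 20 h. Without the 72 h list, 21.8% of regions were called at every stage, by construction a looser demand, and the share called at 1 stage stayed within its interval.

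Percentiles of gene lists moved most with lists of equal number. Of the differences between stages, 9 stayed inside the central 95% of random lists or outside it on the same side, 19 came inside it and 5 turned to the other side. The 5 that turned were endoderm genes 97.9 (20 h to 72 h), ectoderm genes 98.47 (20 h to 72 h), early zygotic genes 100 (20 h to 72 h), homeobox genes 99.03 (20 h to 72 h) and regulatory genes 99.7 (20 h to 72 h). Those that came inside were skeletogenic genes 33.05 (8 h to 12 h), 96.2 (12 h to 20 h) and 7.97 (20 h to 72 h), pigment cell and other mesoderm genes 37.98 (8 h to 12 h), 93.4 (12 h to 20 h) and 44.88 (20 h to 72 h), endoderm genes 45.12 (8 h to 12 h) and 94.62 (12 h to 20 h), ectoderm genes 86.8 (12 h to 20 h), apical genes 89.88 (12 h to 20 h) and 90.35 (20 h to 72 h), early zygotic genes 69.82 (12 h to 20 h), immune genes 6.53 (12 h to 20 h), homeobox genes 44.92 (8 h to 12 h) and 91.2 (12 h to 20 h), signalling genes 28.72 (8 h to 12 h), 79.83 (12 h to 20 h) and 76.97 (20 h to 72 h) and regulatory genes 32.85 (8 h to 12 h). Of the percentiles at single stages, 28 stayed so and 16 came inside: pigment cell and other mesoderm genes 68.75 (8 h) and 97.03 (20 h), endoderm genes 88.2 (8 h) and 84.8 (12 h), ectoderm genes 91.15 (8 h) and 96.15 (12 h), apical genes 82.78 (8 h) and 96.85 (20 h), early zygotic genes 96.17 (8 h), immune genes 90.7 (12 h), gamete genes 74.2 (8 h), homeobox genes 91.65 (8 h) and 88.38 (12 h), signalling genes 83.5 (8 h) and 88.42 (20 h) and regulatory genes 93.93 (12 h). Thinning leaves few elements per gene and removes the different lengths of the lists, and which of the 2 moved the percentiles was not tested. It drops elements whatever their width and was not shown to act as a lower depth would.

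With the gene body only, 32 percentiles at single stages and 25 of differences stayed inside the central 95% or outside it on the same side. At single stages, those inside the central 95% here but not as reported were skeletogenic genes 93.84 (20 h), pigment cell and other mesoderm genes 89.78 (8 h), endoderm genes 90.98 (12 h), ectoderm genes 96.36 (8 h), 89.28 (12 h) and 90.56 (72 h), apical genes 87.4 (8 h), immune genes 96.5 (12 h), gamete genes 70.89 (8 h), signalling genes 96.92 (8 h) and 95.49 (20 h) and regulatory genes 89.11 (12 h). For differences they were skeletogenic genes 10.97 (8 h to 12 h) and 3.97 (20 h to 72 h), pigment cell and other mesoderm genes 10.01 (8 h to 12 h), early zygotic genes 96.22 (12 h to 20 h), immune genes 11.41 (12 h to 20 h), homeobox genes 2.64 (8 h to 12 h) and signalling genes 6.62 (20 h to 72 h). Outside it here but not as reported, for differences, were gamete genes 1.73 (12 h to 20 h). With 50 kb either side, 38 percentiles at single stages and 28 of differences stayed inside the central 95% or outside it on the same side. At single stages, those inside the central 95% here but not as reported were endoderm genes 95.41 (12 h), immune genes 96.26 (12 h) and gamete genes 94.3 (8 h). For differences they were pigment cell and other mesoderm genes 2.67 (8 h to 12 h) and immune genes 19.66 (12 h to 20 h). Outside it here but not as reported were, at single stages, skeletogenic genes 99.68 (8 h), pigment cell and other mesoderm genes 99.34 (72 h) and apical genes 99.45 (12 h), and for differences ectoderm genes 0.02 (8 h to 12 h), apical genes 0.01 (8 h to 12 h) and early zygotic genes 0.08 (8 h to 12 h). With each element given to the nearest gene end only, 35 percentiles at single stages and 29 of differences stayed inside the central 95% or outside it on the same side. At single stages, those inside the central 95% here but not as reported were immune genes 96.54 (12 h) and gamete genes 76 (8 h). Outside it here but not as reported were, at single stages, skeletogenic genes 99.94 (8 h), 98.39 (12 h) and 97.84 (72 h), pigment cell and other mesoderm genes 97.85 (12 h) and 98.69 (72 h), apical genes 100 (12 h) and signalling genes 99.81 (72 h), and for differences ectoderm genes 0.00 (8 h to 12 h), apical genes 0.01 (8 h to 12 h), early zygotic genes 0.00 (8 h to 12 h) and gamete genes 1.87 (12 h to 20 h). The cause was not tested.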

Other observations

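Transfer RNA genes, which RNA polymerase III transcribes, held a gene-end element more often than random placement gave at each of the 4 stages. In this part, the classes of genes, the test by number of libraries and the comparisons of width with other stages were chosen after the results were seen. Of 954 tRNA genes, 65.3% had a gene-end element at 8 h (95% interval 62.2 to 68.3), 51.6% at 12 h (48.4 to 54.7), 41.7% at 20 h (38.6 to 44.9) and 14.0% at 72 h (12.0 to 16.4), against 11%, 6.2%, 7.7% and 0.9% for random placement. Protein-coding genes stood at 49.5%, 39.6%, 43.2% and 12.4%, against 19.5%, 11.4%, 13.8% and 1.7%, and the 2 classes were not tested against each other. Since tRNA genes lie in groups and an element can serve several, they were also joined within 10 kb into 363 clusters, of which 86.5%, 78.5%, 68.9% and 27.8% had an element. No random placement was made for clusters, and a cluster of several genes has more ends to meet. Cluster shares are thus not measures of enrichment. The 247 tRNA genes alone in their cluster had an element in 82.2%, 74.5%, 66.0% and 24.7% of cases. No random placement was made for these genes alone.

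Of 256 snRNA genes, which encode RNAs of the spliceosome, 27.7%, 23.8%, 16.4% and 4.3% had a gene-end element at 8 h, 12 h, 20 h and 72 h, against 10.4%, 6.0%, 7.1% and 0.9% for random placement. Joined within 10 kb they formed 58 clusters, of which 74.1%, 65.5%, 63.8% and 17.2% had one, again without a random value for clusters. The largest cluster held 68 of the 256 genes, so it weighs heavily in the shares of genes. The 46 snRNA genes alone in their cluster stood at 67.4%, 58.7%, 56.5% and 15.2%, again without a random value of their own. Long noncoding RNA genes, 3231 in number, stood at 27.8%, 17.3%, 16.8% and 2.6%, nearer to the 18.5%, 10.6%, 12.8% and 1.5% of random placement. The 471 pseudogenes stood at 17.6%, 13%, 8.5% and 2.8%, against 13.4%, 7.8%, 9.0% and 1.0%. The rRNA genes stood at 9.3%, 10.4%, 8.2% and 4.4%, against 12.9%, 7.3%, 8.0% and 1.1%, and snoRNA genes at 7.9%, 7.9%, 4.0% and 2.0%, against 11.1%, 6.6%, 8.0% and 0.9%.

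The 72 h list held far fewer elements than the others, and a lower number of libraries does not account for it, since the 8 h list came from as many libraries, of fewer biological replicates, and held 12.69 times the elements. The widest quintile of 20 h elements was found at 72 h 12.7 times as often as the narrowest, but wide elements were found again more often at 12 h (4.9 times) and 20 h (2.8 times) too, and width was not shown to stand for strength, so this decides nothing about which elements were called. The share of elements absent from all earlier lists differed by -30.3 percentage points between 72 h and 20 h. The bound set for this test was wrong by design, since elements used at 72 h alone would lengthen the list, and the 72 h list faced 3 earlier lists and the 20 h list 2. Read depth is unknown, and a shallow measurement and a true loss of elements both stay open.

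At 12 h, 6308 elements called at 8 h and 20 h were not called. Shifted borders do not account for most of them, since 6.5% had a 12 h element within 500 bp, against 3.3% for random placement. Their median width at 8 h differed by -280 bp from that of elements called at all 3 stages, 630 against 910 bp. Elements called at 8 h and 12 h but not at 20 h were narrower in the same way, with a median of 650 bp, so width does not single out 12 h. Weak elements missed at 12 h, a difference in depth and a pause in use all stay open.

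Regulatory genes held more elements in their neighbourhood than genes of like length. Lists of 211 other curated genes had a mean of 3.58 at 8 h, between 2.71 for random lists and 4.76 for regulatory genes. These others include developmental regulators such as GATAc, blimp1/krox, erg and gcm, so their mean does not separate curation from regulatory function. Curation does not account for all of the excess at 8 h, where the regulatory mean lay at the 99.96th percentile of those lists. That percentile was 81.86 at 12 h and 100 at 20 h and 72 h. Elements in the flanks do not account for all of the excess at 8 h, where the gene body alone gave the 100th percentile. The body alone gave 89.11 at 12 h, 100 at 20 h and 99.99 at 72 h. Its mean at 8 h was 2.11, against 1.22 for random lists, so part of the excess lay in the flanks. Whether elements of neighbouring genes made up that part cannot be told from these numbers. A denser set of elements around regulatory genes at 8 h, 20 h and 72 h is consistent with these values and with the 97.75, 100 and 100 of lists of equal number (93.93 at 12 h), and the part of depth stays open.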
